A study of Homo sapiens with 12 samples.

How the data were processed

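The data were 12 RNA-seq libraries of A2058 melanoma cells, 3 each of untreated cells, cells given a control siRNA and cells given either of 2 SOX10 siRNAs. Per the labels' protocols, cells were transfected at 12.5 nM with a lipid reagent, RNA was extracted with a column kit after 96 hours, and libraries were made with a low-input full-length cDNA kit followed by transposase-based tagmentation. The submitters' processing notes name bcl2fastq and DRAGEN. Their versions, the annotation, the genome build and the use of strand are not given in the sources used here. The authors deposited 1 table of TPM for 61587 genes with coordinates and annotation, and each library's TPM sum to 1000000. TPM are scaled by gene length and by the library's total, so a rise in a few abundant genes lowers all others, and TPM keep neither read counts nor depth. FTL alone took 30299 to 38904 TPM in the siSOX10_1 libraries against 11381 to 12188 TPM in the siCNTL libraries. No counting interval can be given.

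Groups and batches were taken from the labels, which give each replicate number as a batch. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these libraries. Of the table's gene identifiers 94.8% were found in GENCODE v29 (GRCh38), of which 99.9% overlapped the same place and 72.7% had identical start and end, so coordinates are given as GRCh38, as the table lists them.

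Values were taken as log2(TPM + 1), and genes with at least 1 TPM in at least 3 libraries were kept (15738). The main test was limma 3.58.1 in R 4.3.3 (linear model on group means of all 12 libraries, empirical Bayes with trend and robust options, 8 residual degrees of freedom) with Benjamini-Hochberg adjustment and a threshold of 0.05. The planned count-based tests were not run, since the table holds no counts. The 5 comparisons were each SOX10 siRNA against siCNTL, their mean against siCNTL, siSOX10_2 against siSOX10_1, and siCNTL against untreated. The labels say that the number marks a shared batch, so the numbers pair the libraries. Deviations from the group means correlated with a median r of 0.179 over 18 pairs of the same batch and -0.0974 over 36 pairs of different batches. The fit was repeated with the batch as a block.

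Gene lists (28) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists. Of the calls with the preset correlation in the mean of both siRNAs, 1 held with the estimated one. The fry test asks whether a list's members changed in a common direction, not whether they changed more than other genes. With the batch as a block, it passed in the mean of both siRNAs for all lists tested except 4. These were cholesterol (fry adjusted p = 0.0529), mitochondrially encoded (0.200), BCL2 (0.876) and unfolded protein (0.928). Taken without regard to direction, fry passed for cholesterol (adjusted p = 1.03e-07), BCL2 (1.83e-06) and unfolded protein (1.83e-06). It did not pass for mitochondrially encoded (0.125). Below, a list that passed or did not pass did so by camera. Counts of members use the adjusted p over all genes tested. Some genes stand in more than 1 list, such as CAV1. Some genes of the lists are counted but are not reported here by name.

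The genes named were fixed by a rule: the title's genes, the 10 that rose and 10 that fell with the largest smaller change of the 2 siRNAs (called with both, mean TPM of at least 5), the 4 highest and 4 lowest called genes in the direct comparison of the siRNAs, and up to 4 called members per list with the largest change. MITF, TYR, FTL, POLR2F, UTS2, KEAP1, NFE2L2 and the members of sets described in the closing section were chosen after their values were seen, as were the members named only because 5 or fewer of a list rose or fell.

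The fit was tested on simulated data for the 15738 genes with 200 genes changed in both SOX10 siRNA groups, in 5 runs. The 200 were drawn from genes averaging above 5 TPM on the log2 scale, so recovery of lower genes was not tested. Noise was drawn independently for each gene and without batches. For siSOX10_1 vs siCNTL, 70% of 2-fold and 96% of 4-fold changes were recovered, with 10.6 false calls on average. Alternatives were the batch as a block, leaving out each library, only the compared groups in the fit, no filter, a filter at 5 TPM, pseudocounts of 0.1 and 5, median-of-ratios scaling, quantile normalization, limma without trend and robust options, a fold of at least 2, an adjusted p under 0.01 and untreated cells as the control. Leaving out batch 3 was added after seeing the data. Reactome sets given in the table, without the smallest and largest (727 sets), were tested with camera.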

Results

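RNA was measured in A2058 cells, an established human melanoma line, in 12 libraries that fall into 4 groups of 3. The groups were untreated cells, cells transfected with a negative control siRNA (siCNTL), and cells transfected with either of 2 siRNAs against SOX10 (siSOX10_1 and siSOX10_2). The siRNAs were used at 12.5 nM and RNA was taken after 96 hours. Each group had 1 library in each of 3 batches. SOX10 is a transcription factor of the neural crest and of melanocytes. The series title names it together with IRF1, ITGA3, EPHA2 and FAK (the product of PTK2), so the question addressed here is how these genes and the rest of the transcriptome changed when SOX10 was lowered. Values are TPM (transcript abundances scaled to the same total in every library). TPM keep no sequencing depth, so the depth of each library is unknown. Between 20396 and 23564 genes had a value above 0 per library, and 13648 to 15333 reached 1 TPM. Of 61587 genes, 15738 were tested. Values are mean ± SD of 3 libraries, and log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, ± their standard error from limma.

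SOX10 (chromosome 22, 37970686 to 37987422, minus strand, GRCh38) was at 26.9 ± 5.14 TPM in untreated cells and 31.8 ± 4.40 TPM with siCNTL. It was at 9.64 ± 5.47 TPM with siSOX10_1 and 8.34 ± 3.83 TPM with siSOX10_2, which is 30.3% and 26.2% of the siCNTL mean. The log2 fold changes were -1.80 ± 0.421 (limma adjusted p = 0.00728) and -1.90 ± 0.421 (adjusted p = 0.00486), and all 6 SOX10 siRNA libraries lay below all 6 control libraries. With siSOX10_1 the batch 1, 2 and 3 libraries had 12.8, 12.8 and 3.32 TPM, and with siSOX10_2 they had 11.8, 8.95 and 4.24 TPM. SOX10 lies across POLR2F, which is transcribed from the opposite strand and also fell (617 ± 33.7 TPM with siCNTL, log2 fold change -0.50 in the mean of both siRNAs, adjusted p = 0.000180). Whether the counting used strand is not given in the sources used here, so reads of this pair may not be separable.

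ITGA3 (chromosome 17, 50055968 to 50090481), an integrin alpha chain that pairs with integrin beta 1, rose from 5.40 ± 1.07 TPM with siCNTL (5.22 ± 0.553 TPM in untreated cells) to 182 ± 36.0 TPM with siSOX10_1 and 153 ± 12.5 TPM with siSOX10_2. These are 33.7-fold and 28.4-fold differences of the means, with log2 fold changes of 4.83 ± 0.172 (limma adjusted p = 2.30e-09) and 4.60 ± 0.172 (adjusted p = 2.44e-09). EPHA2 (chromosome 1, 16124337 to 16156069), a receptor tyrosine kinase for ephrins, rose from 9.53 ± 0.758 TPM (untreated 9.72 ± 1.63 TPM) to 30.8 ± 1.63 and 42.2 ± 8.92 TPM (adjusted p = 3.75e-05 and 4.63e-06). PTK2 (chromosome 8, 140657900 to 141002216) rose less, from 80.2 ± 12.2 TPM (untreated 86.8 ± 17.9 TPM) to 116 ± 9.64 TPM (log2 fold change 0.54 ± 0.152, adjusted p = 0.0190) and 138 ± 12.1 TPM (0.78 ± 0.152, adjusted p = 0.00187). Its call with siSOX10_1 was lost without siCNTL replicate 1 (adjusted p = 0.0878), without siSOX10_1 replicate 1 (0.0502) or 2 (0.0694), under median-of-ratios scaling (0.0521), with no filter on low genes (0.0518) and against untreated cells (0.0504). IRF1 (chromosome 5, 132440440 to 132508719), a transcription factor of interferon responses, was at 47.2 ± 18.7 TPM with siSOX10_1 and 82.8 ± 19.4 TPM with siSOX10_2, against 8.53 ± 3.69 TPM in untreated cells. It overlaps the antisense transcript IRF1-AS1, which had a mean of 5.24 TPM over all libraries.

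The siCNTL libraries themselves spread widely for IRF1, at 8.68, 39.3 and 5.79 TPM in batches 1, 2 and 3. IRF1 rose with siSOX10_2 (log2 fold change 2.57 ± 0.585, limma adjusted p = 0.00749, and 3.34 without siCNTL replicate 2, adjusted p = 0.000106), while with siSOX10_1 its log2 fold change of 1.72 ± 0.585 did not pass (adjusted p = 0.0514). The difference between the siRNAs was not significant (0.85 ± 0.585, adjusted p = 0.568). With the batch as a block siSOX10_1 passed (adjusted p = 0.0153), as it did without siCNTL replicate 2 (log2 fold change 2.49, adjusted p = 0.000806) and without siSOX10_1 replicate 3 (2.06, adjusted p = 0.0479), under median-of-ratios scaling (0.0401) and against untreated cells (0.0134). It passed narrowly with a filter at 5 TPM (0.0448), a pseudocount of 5 (0.0487) and without trend and robust options (0.0491). The adjusted p was higher without siCNTL replicate 1 (0.157) or 3 (0.156) and without siSOX10_1 replicate 1 (0.148) or 2 (0.119). It was 0.131 with only the compared groups in the fit and 0.0884 with no filter on low genes. Without the 4 libraries of batch 3, chosen after seeing the data, neither siRNA passed (log2 fold changes 1.55 and 2.24, adjusted p = 0.204 and 0.0916).

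**Figure D1:**
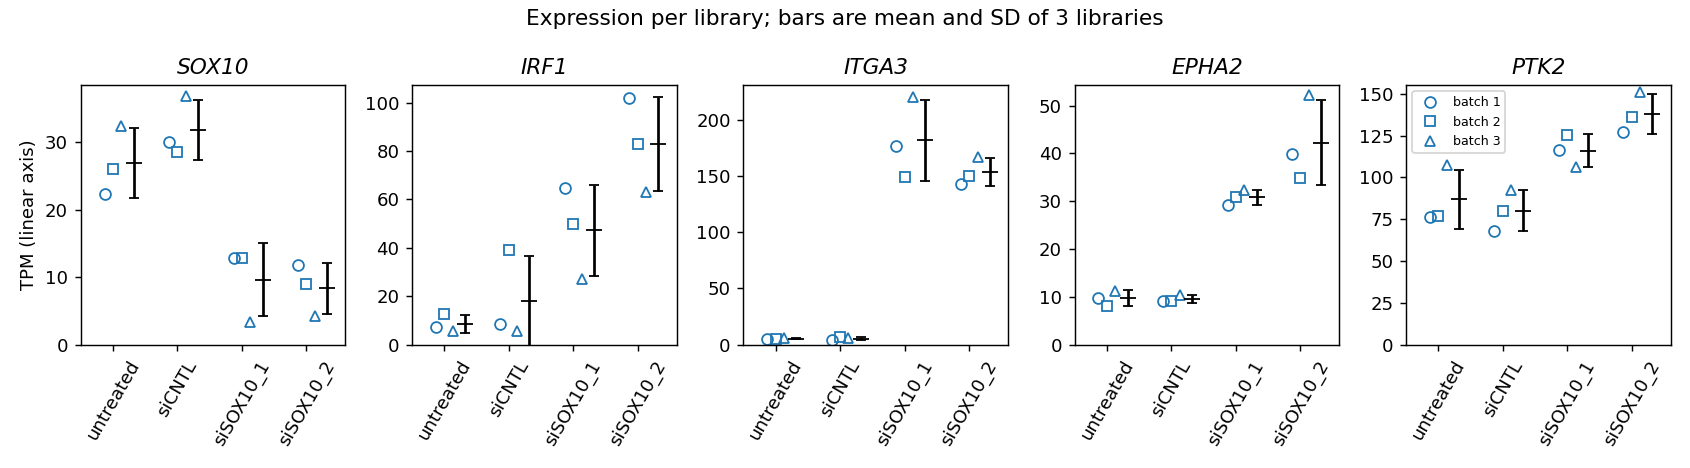
TPM (linear axes from 0) of the genes named in the series title in each of the 12 libraries, by group, with the marker showing the batch; black bars are the mean and SD of 3 libraries, and the lower end of the siCNTL bar for IRF1 lies below 0. ITGA3 was at 5.40 ± 1.07 TPM with siCNTL and 182 ± 36.0 TPM with siSOX10_1, and 1 siCNTL library had 39.3 TPM of IRF1.

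Across all genes, siSOX10_1 changed 4291 genes against siCNTL (2451 higher, 1840 lower) and siSOX10_2 changed 4539 (2898 higher, 1641 lower) at a limma adjusted p under 0.05. Both siRNAs changed 3165 genes the same way, 1908 higher and 1257 lower, and 4 genes the opposite way (LAPTM4A, SRI, ZDHHC12 and an unnamed gene, listed after their values were seen). In the mean of both siRNAs, 5208 genes differed from siCNTL, 3185 higher and 2023 lower. Of the 10 genes with the strongest rise, IL1B, the cytokine interleukin 1 beta, went from 0.629 ± 0.483 TPM to 219 ± 34.3 and 660 ± 140 TPM. PTGES, a prostaglandin E synthase, went from 7.20 ± 1.20 to 768 ± 65.7 and 1080 ± 82.3 TPM. The others were the chemokine CCL5, the gelatinase MMP9, the keratin KRT81, ANGPTL4, the integrin ITGA1, HSD11B1, OLFML2B and ID1, with log2 fold changes of 4.63 (ID1 with siSOX10_2) to 6.70 (CCL5 with siSOX10_2).

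The genes with the strongest fall were GJB1, RLBP1, TRPM1, FABP7, CAPN3, FXYD3, HPGD, MLANA, CPN1 and SGCD. GJB1, a gap junction protein of Schwann cells, fell from 82.7 ± 20.5 TPM to 5.92 ± 4.39 and 6.46 ± 4.07 TPM, and HPGD, a prostaglandin dehydrogenase, from 29.5 ± 0.742 to 2.45 ± 1.57 and 2.12 ± 1.05 TPM. FABP7 and FXYD3 varied most between libraries: with siSOX10_1, FABP7 passed at adjusted p = 0.0256 but not without siCNTL replicate 1 (0.0846), siCNTL replicate 2 (0.0799) or siSOX10_1 replicate 3 (0.0900), and FXYD3 passed at 0.0221 but not without the same libraries (0.0763, 0.0623 and 0.0774). With siSOX10_2, FABP7 passed at 0.0179 but not without siCNTL replicate 1 (0.0616), siCNTL replicate 2 (0.0595) or siSOX10_2 replicate 3 (0.0652), and FXYD3 passed at 0.0160 but not without siCNTL replicate 1 (0.0586). The surplus of higher over lower calls depended on scaling. Median-of-ratios scaling moved the median of all genes by -0.11 on the log2 scale for siSOX10_2, where 2192 genes were then higher and 2202 lower, and by -0.038 for siSOX10_1, where 2200 were higher and 2173 lower.

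**Figure D2:**
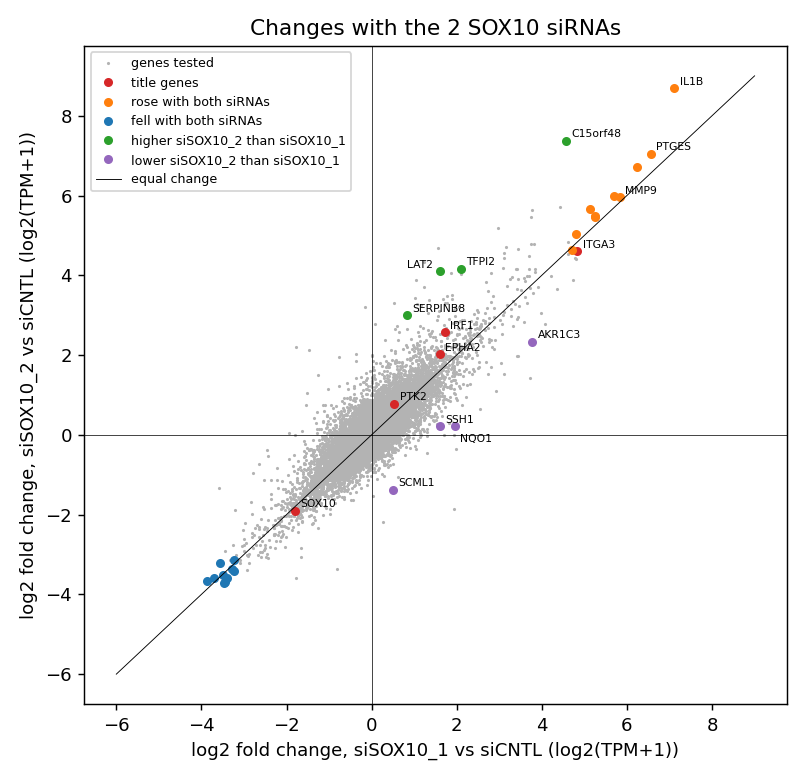
Log2 fold changes against siCNTL of 15738 genes, siSOX10_1 on the horizontal and siSOX10_2 on the vertical axis, on the log2(TPM + 1) scale; each dot is a gene, colours mark the genes chosen by rule, the 10 genes that fell most are blue and the line is equal change. IL1B lies at 7.11 and 8.69, and NQO1 at 1.96 and 0.22.

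The changes with the 2 siRNAs correlated across genes (Pearson r = 0.861, genes are not independent replicates). Both comparisons share the siCNTL libraries. In groups simulated without any change, with all 12 libraries redrawn, siCNTL included, r was 0.501. Sharing 1 control group of like size and spread fixes r near that value. A mean of 0.01 genes was called higher in both and 0.01 lower in both. Genes were drawn independently and without batches, so the simulated values leave out correlation between genes. The covariance was 0.501 against 0.0474 in the simulation, a difference of 0.453. Independent lists of these sizes would share 451 higher and 192 lower genes, a value that leaves out the shared controls. With siSOX10_2 set against untreated cells instead, so that no control library was shared, r was 0.774, and with siSOX10_1 set against untreated cells it was 0.806. These left 1771 and 1786 genes called higher in both.

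Genes of the melanocyte program fell as a group. Of 27 measured members of the melanocyte differentiation and pigmentation list, 22 fell and 2 (TFAP2A and CDH3) rose in the mean of both siRNAs, or 23 and 3 adjusted over the list alone (camera adjusted p = 9.70e-11, and 0.227 with an estimated correlation). TYR, the tyrosinase of melanin synthesis, went from 1072 ± 98.4 to 179 ± 117 and 160 ± 97.7 TPM, with 44.2 and 48.5 TPM in the batch 3 libraries of the 2 siRNAs, and MITF, the lineage transcription factor, from 378 ± 76.6 to 100 ± 55.8 and 72.4 ± 38.4 TPM. CAPN3 and RXRG fell in the same way, with log2 fold changes of -3.56 and -3.16. In the libraries as a whole, the second principal component (12.3% of variance) set batch 3 of siCNTL and of both SOX10 siRNAs apart from batches 1 and 2. Of 22 neural crest and glial genes, 15 fell, among them S100B (-2.40), and 4 rose (ZEB2, PAX3, NGFR and L1CAM), the same counts adjusted over the list alone (adjusted p = 4.05e-05, and 0.340 with an estimated correlation). The 15 include SOX10, the target of the siRNAs, and SOX5, SOX6 and SOX8, which are counted again in the next list. In the SOX family list 3 of 7 measured members fell, SOX5, SOX6 and SOX8, and the same 3 adjusted over the list alone (camera adjusted p = 0.0891).

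Genes of the undifferentiated, invasive melanoma state rose. Of 27 measured members 24 rose and none fell, as when adjusted over the list alone (camera adjusted p = 1.65e-12, and 0.0924 with an estimated correlation). AXL, a receptor tyrosine kinase, went from 5.45 ± 1.22 to 32.1 ± 12.8 and 41.3 ± 17.2 TPM. DKK1, CCN1 and LOXL2 had log2 fold changes of 4.05, 3.96 and 3.67. Of 16 mesenchymal transition regulators and cadherins 10 rose, with CDH2 (N-cadherin) at 2.24, and 1 fell, SNAI2 at -1.71, with the same counts adjusted over the list alone (camera adjusted p = 0.00714, and 0.105 with an estimated correlation).

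Adhesion genes moved in both directions. Of 20 measured integrin genes 9 rose and 4 fell (ITGB8, ITGAM, ITGAE and ITGB3), as when adjusted over the list alone (camera adjusted p = 0.0409, 0.282 with an estimated correlation and 0.0586 with the batch as a block). With siSOX10_1 alone the list passed (median 0.65, adjusted p = 0.00473, and 0.160 with an estimated correlation), and with siSOX10_2 alone it did not (median 0.18, adjusted p = 0.128). ITGA1, ITGA3, ITGA11 and ITGA5 rose most, with log2 fold changes of 5.37, 4.72, 4.31 and 2.79. The list test also missed 0.05 without siCNTL replicate 3 (0.0703), without siSOX10_1 replicate 3 (0.0720), without batch 3 (0.103) and against untreated cells (0.0849). Of 33 focal adhesion components 19 rose and 1 fell, or 20 and 2 adjusted over the list alone (adjusted p = 7.55e-05, and 0.199 with an estimated correlation). CAV1 and TLN1 (talin) rose by 3.18 and 1.84 on the log2 scale, and NEDD9, a scaffold of FAK signalling, fell by 1.40. Of 13 Eph receptors and ephrins 5 rose (EPHA2 most, then EFNB2, EFNB1, EPHB3 and EPHB4), the same 5 adjusted over the list alone, and the list test did not pass (adjusted p = 0.222). EPHB3 (0.75, adjusted p = 0.0462) lost its call in 9 of the 12 fits without 1 library, with adjusted p up to 0.217. Of 30 extracellular matrix and protease genes 19 rose and 4 fell (LAMA4, MMP8, MMP15 and TIMP2), or 20 and 4 adjusted over the list alone (adjusted p = 2.57e-06, and 0.153 with an estimated correlation), with the collagenase MMP1 going from 63.3 ± 23.5 to 832 ± 183 and 1704 ± 271 TPM and LAMB3, a laminin chain, from 1.45 ± 0.546 to 30.6 ± 3.66 and 55.4 ± 22.1 TPM.

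Inflammatory genes rose as well. Of 21 measured NF-kB cytokines and chemokines 19 rose and none fell (20 rose adjusted over the list alone), and this was the list whose call held with an estimated correlation (camera adjusted p = 2.96e-12, and 0.00962 with an estimated correlation). CXCL8 (interleukin 8) went from 19.8 ± 9.63 to 418 ± 127 and 1043 ± 461 TPM, and IL11 had a log2 fold change of 4.31. Of 23 interferon gamma and IRF1 response genes 13 rose and 1 fell (GBP2), or 14 and 1 adjusted over the list alone (adjusted p = 0.00714, and 0.322 with an estimated correlation), with TNFSF10 (TRAIL) at 2.44 and the chemokine CXCL10 at 1.49. Of 20 MHC class I genes 12 rose and none fell, or 14 rose adjusted over the list alone (adjusted p = 0.00131, and 0.153 with an estimated correlation). With siSOX10_1 12 rose (adjusted p = 4.77e-05, and 0.0783 with an estimated correlation). With siSOX10_2 7 rose and the list did not pass (0.0545), but did with the batch as a block (0.0444, and 0.408 with an estimated correlation). HLA-B went from 172 ± 79.0 to 523 ± 179 and 529 ± 238 TPM. HLA genes are near-identical to one another and reads may be split between them. Of 35 type I interferon-stimulated genes 13 rose and 2 fell (HERC6 and IFI35), as when adjusted over the list alone, and the list did not pass (adjusted p = 0.0923). With siSOX10_2 alone it passed (median 0.54, adjusted p = 0.0242, and 0.579 with an estimated correlation), and with siSOX10_1 alone it did not (median 0.14, adjusted p = 0.316). BST2 (tetherin) was among those that rose, from 45.3 ± 14.9 to 432 ± 81.4 and 368 ± 139 TPM. In the mean of both siRNAs the list passed without siCNTL replicate 2 (adjusted p = 0.0232), the library with high IRF1, without siSOX10_2 replicate 3 (0.0307), with no filter on low genes (0.00766) and against untreated cells (0.0461), all with the preset correlation (0.684 with an estimated correlation and all libraries). In the double-stranded RNA sensing list 5 of 12 measured members rose, EIF2AK2 (PKR) at 0.77 and ADAR at 0.65 among them, and 6 rose adjusted over the list alone (camera adjusted p = 0.164). The ADAR call was lost without siCNTL replicate 1 (adjusted p = 0.0531).

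Mitotic genes rose by moderate amounts. Of 28 G2/M and mitosis genes 26 rose and none fell, or 27 rose adjusted over the list alone (camera adjusted p = 9.70e-11, and 0.227 with an estimated correlation), with TOP2A going from 48.9 ± 13.8 to 132 ± 2.71 and 118 ± 5.82 TPM and MKI67 from 10.8 ± 1.83 to 33.3 ± 6.46 and 25.9 ± 2.86 TPM. Of 28 G1/S and replication genes 9 rose, as when adjusted over the list alone, RRM2 most at 1.61 and TK1 at 1.03 (adjusted p = 0.0923, 0.427 with an estimated correlation, and 0.0101 with no filter on low genes). The CDK inhibitors CDKN2C and CDKN2B rose by 2.44 and 2.21 on the log2 scale and CDKN1C fell by 1.61, within a list in which 10 of 28 rose and 2 fell (CDKN1C and TP53I3), or 11 and 3 adjusted over the list alone, and which did not pass (adjusted p = 0.104, 0.488 with an estimated correlation, and 0.0295 with no filter). In the MAPK list 8 of 21 rose, FOSL1 at 3.54 and CCND1 (cyclin D1) at 1.76, and 4 fell (ETV4, ETV5, MYC and FOS), or 9 and 4 adjusted over the list alone. Its adjusted p was 0.0891 (0.454 with an estimated correlation), and with the preset correlation it passed without siCNTL replicate 2 (0.0311), with no filter (0.0144) and against untreated cells (0.0496). Of 16 receptor tyrosine kinases 8 rose, with FLT1 at 1.86 and FGFR1 at 1.40, and 3 fell (ERBB3 at -1.62, ROR1 and TYRO3), or 8 and 4 adjusted over the list alone (adjusted p = 0.165).

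Of the other lists, the mitochondrially encoded one passed camera in the mean of both siRNAs, and the rest did not pass or held few measured genes. In the BCL2 family MCL1 rose (1.29) and BCL2A1, a pro-survival member, fell (-1.98) of 14 measured, the same 2 adjusted over the list alone (adjusted p = 0.896). Its median was 0.19 while its mean, -0.0015, and the test pointed down. In the unfolded protein and ATF4 list 5 of 24 rose, DDIT4 at 1.24 and CREB3L2 at 0.77 among them, and 1 fell, the serine synthesis enzyme PSAT1 at -1.97, as when adjusted over the list alone (adjusted p = 0.967). Its median was 0.094, its mean -0.0010, and the median turned to -0.0062 under quantile normalization. In the cholesterol list 3 of 24 rose (SQLE at 0.89, HMGCS1 and MSMO1) and 6 fell (MYLIP at -1.68 most), as when adjusted over the list alone (adjusted p = 0.0891, 0.448 with an estimated correlation, 0.0481 under median-of-ratios scaling and 0.0433 with no filter, and 0.239 with siSOX10_2 alone). With siSOX10_1 alone it passed (0.0225, and 0.395 with an estimated correlation). The direct comparison of the siRNAs did not pass for the cholesterol list. With the batch as a block its median there was 0.20 (camera adjusted p = 0.0583, and 0.548 with an estimated correlation). The median of -0.12 in the mean of both siRNAs turned to 0.019 against untreated cells. In the RNA interference machinery 2 of 13 rose (TNRC6B and AGO2) and 1 fell (AGO4), as when adjusted over the list alone (adjusted p = 0.954). These calls were lost without siCNTL replicate 1 for TNRC6B (0.0589), replicate 3 for AGO2 (0.120) and replicates 2 or 3 for AGO4 (0.0729 and 0.104). Markers of other cell types were also followed. Of 6 measured fibroblast markers 3 rose (COL1A1 at 3.33, FBLN1 and FAP) and 1, LUM, fell, as when adjusted over the list alone (adjusted p = 0.229, 0.427 with an estimated correlation, and 0.0311 with no filter). The FAP call (adjusted p = 0.0214) was lost without siCNTL replicate 3 (0.111). Of 4 keratinocyte and epithelial markers 3 rose, KRT8 at 0.99, KRT18 and KRT10, the same 3 adjusted over the list alone (adjusted p = 0.152). The KRT10 call (adjusted p = 0.0386) was lost in 7 of the 12 fits without 1 library, with adjusted p up to 0.125. The leukocyte marker CD68 rose (0.56) and FCER1G fell (-0.72, adjusted p = 0.0392, lost in 7 of the 12 fits without 1 library with adjusted p up to 0.183). These 2 and the endothelial marker TIE1 were too few for a list test. TIE1 did not pass in the mean of both siRNAs (0.86, adjusted p = 0.0531), but did with the batch as a block (0.0475), against untreated cells (0.0145), and without siCNTL replicate 2 (0.0311), siSOX10_1 replicate 2 (0.0345) or siSOX10_2 replicate 2 (0.0326). Of 13 mitochondrially encoded mRNAs 4 fell (MT-CYB, MT-ATP6, MT-CO3 and MT-CO2), as when adjusted over the list alone (adjusted p = 0.0124, 0.488 with an estimated correlation, 0.0625 without siCNTL replicate 1 and 0.193 under quantile normalization). MT-CYB fell by 0.66 on the log2 scale, and the call of MT-CO3 was lost without siCNTL replicate 1 (0.0584), that of MT-ATP6 in 3 and that of MT-CO2 in 8 of the 12 fits without 1 library (adjusted p up to 0.154 and 0.183). The list's median of -0.26 turned to 0.17 against untreated cells. Mitochondrially encoded transcripts made up 1.91 ± 0.150% of TPM with siCNTL, 1.57 ± 0.165% with siSOX10_1, 1.77 ± 0.186% with siSOX10_2 and 1.496 ± 0.347% in untreated cells. The list passed with siSOX10_1 (adjusted p = 0.00473, and 0.481 with an estimated correlation) but not with siSOX10_2, where no member was called (0.0709), and the direct comparison of the siRNAs did not pass for it (0.120).

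**Figure D3:**
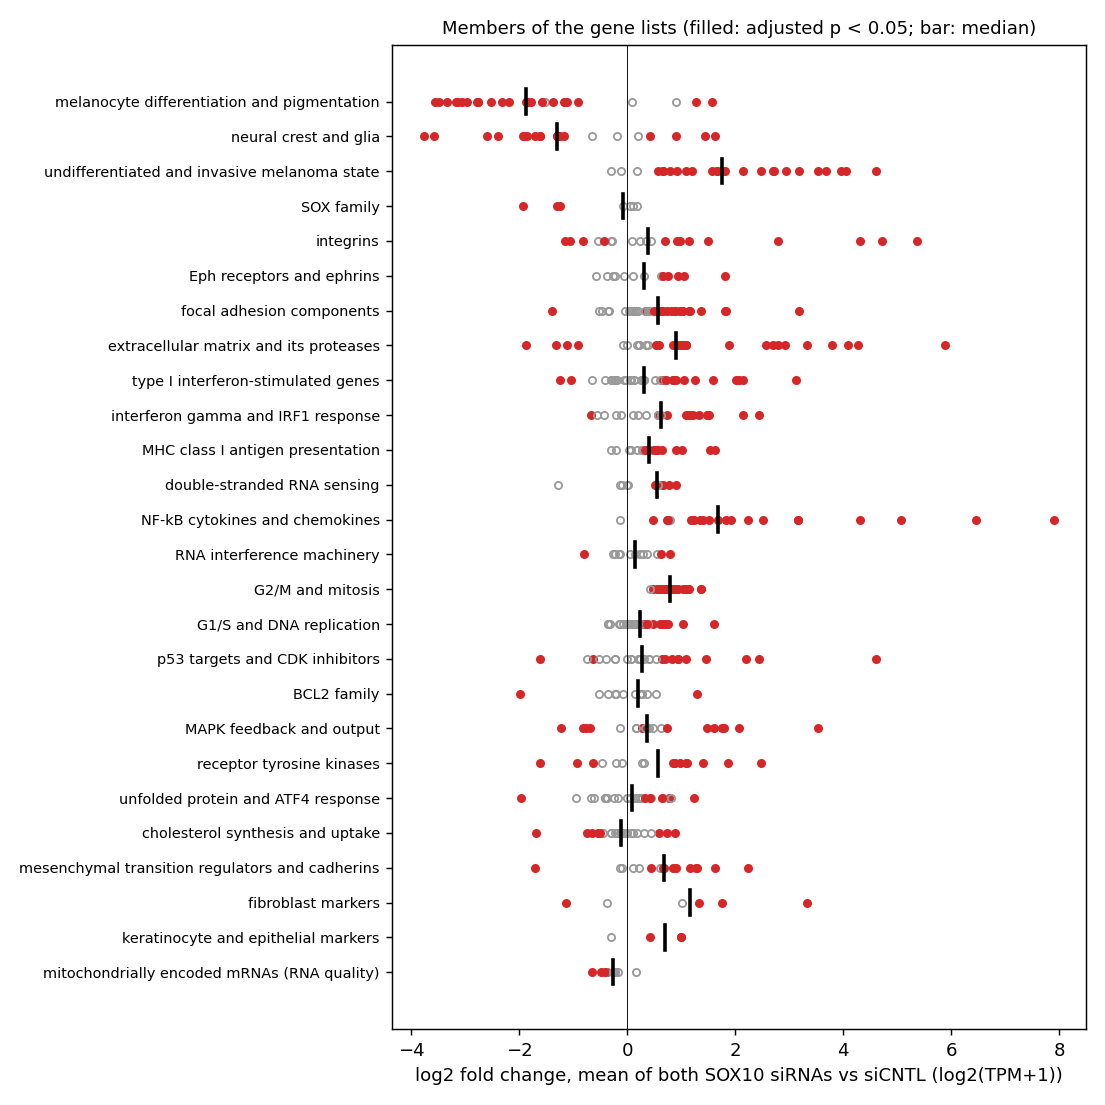
Log2 fold changes in the mean of both SOX10 siRNAs against siCNTL (log2(TPM + 1) scale) of the measured members of each gene list with at least 3 measured members; filled dots had a limma adjusted p under 0.05 and black bars are medians. The medians were -1.88 for the melanocyte list and 1.75 for the invasive state list.

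Set directly against each other, the siRNAs differed in 245 genes, 168 higher and 77 lower with siSOX10_2, and in 488 genes with the batch as a block. The balance of directions turned with scaling, to 105 higher and 131 lower under median-of-ratios scaling and 145 higher and 183 lower under quantile normalization. TFPI2, a protease inhibitor, was at 128 ± 15.8 TPM with siSOX10_1 and 537 ± 58.6 TPM with siSOX10_2 (log2 fold change 2.06 ± 0.139, limma adjusted p = 2.75e-05). C15orf48, LAT2 and SERPINB8 were also higher with siSOX10_2. NQO1, an antioxidant quinone reductase, was at 10775 ± 563 TPM with siSOX10_1 against 3445 ± 1376 TPM with siSOX10_2 and 2767 ± 19.6 TPM with siCNTL (siSOX10_2 vs siSOX10_1, -1.74 ± 0.249, adjusted p = 0.00968), and SCML1, AKR1C3 and SSH1 were also lower with siSOX10_2. NQO1 with siSOX10_2 did not pass against siCNTL (0.22, adjusted p = 0.566), but did without siSOX10_2 replicate 3 (0.61, adjusted p = 0.000221). With only the 2 groups in the fit 29 genes were called, and C15orf48, SCML1, NQO1 and SSH1 did not pass (adjusted p = 0.0773, 0.0905, 0.0854 and 0.0613). The count rested on few libraries: it was 79 without siSOX10_1 replicate 1, 100 without siSOX10_1 replicate 2, 148 without siSOX10_1 replicate 3, 152 without siSOX10_2 replicate 1, 94 without siSOX10_2 replicate 2 and 84 without siSOX10_2 replicate 3. The AKR1C3 call (adjusted p = 0.0488) was lost in 10 of the 12 fits without 1 library, and the SERPINB8 call (0.0307) in each of the 6 fits that left out a SOX10 siRNA library. Of the lists, NF-kB cytokines were higher with siSOX10_2 (median 0.97, 5 of 21 called, IL1B, CCL20, CXCL1, IL6 and TNFAIP2, camera adjusted p = 1.50e-05, and 0.102 with an estimated correlation). The tests of 4 other lists passed with few or no members called: MHC class I towards lower values (median -0.20, 1 of 20 called, ERAP2, adjusted p = 0.000164, and 0.148 with an estimated correlation), neural crest towards lower values (median -0.22, none of 22 called) and type I interferon-stimulated genes towards higher values (median 0.34, 1 of 35 called, IRF9), both at 0.0116 and at 0.804 with an estimated correlation, and integrins towards lower values (median -0.0042, none of 20 called, 0.0446, and 0.449 with an estimated correlation). These medians kept their direction under median-of-ratios scaling and quantile normalization.

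Transfection of the control siRNA gave no call against untreated cells (0 of 15738 genes by limma, with 581 at an unadjusted p under 0.05, and 0 calls and 947 with the batch as a block). The lowest adjusted p was 0.729. SOX10 was not called in this comparison, at 0.24 ± 0.421 on the log2 scale. Without batch 3, an alternative chosen after seeing the data, 20 genes were called. Mitochondrially encoded mRNAs had a median log2 fold change of 0.45 here with no member called (camera adjusted p = 4.97e-11, and 0.950 with an estimated correlation), and G1/S genes had a median of -0.14 with no member called (camera adjusted p = 0.0151, and 0.950 with an estimated correlation).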

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

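Of the tests below, those of library scaling, of batch 3 (apart from the one on the abundance of all genes that fell) and of siCNTL replicate 2 were chosen only after related values had been seen. The other tests were set before their results were seen.

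Several named genes responded differently to the siRNAs by the direct test of siSOX10_2 against siSOX10_1 (log2 fold change, limma adjusted p). Higher with siSOX10_2 were C15orf48 (2.80, adjusted p = 0.00969), LAT2 (2.51, 0.000892), SERPINB8 (2.16, 0.0307), TFPI2 (2.06, 2.75e-05), IL1B (1.57, 0.0118) and HMGCS1 (0.72, 0.0337). Lower with siSOX10_2 were SCML1 (-1.87, 0.00821), NQO1 (-1.74, 0.00968), AKR1C3 (-1.45, 0.0488), SSH1 (-1.40, 0.0044) and LUM (-0.96, 0.0183).

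NQO1, AKR1C3 and the ferritin gene FTL (-1.28, adjusted p = 0.0155) are known targets of the transcription factor NRF2 and were all lower with siSOX10_2 than with siSOX10_1. In a list of 28 other measured NRF2 targets the median log2 fold change was -0.57, 27 were lower and 6 were called, SRXN1 and TXNRD1 among them (camera with an estimated correlation, unadjusted p = 0.0121). Higher NRF2 activity with siSOX10_1 than with siSOX10_2 remains a hypothesis. Against siCNTL the median of these targets was 0.39 with siSOX10_1 and -0.16 with siSOX10_2. The Reactome sets of nuclear events mediated by NFE2L2 (the gene of NRF2) and of the KEAP1-NFE2L2 pathway also pointed to lower values with siSOX10_2. Their medians were -0.32 (5 of 15 genes called lower) and -0.052 (5 of 27). The first set holds NQO1, so it partly restates the pattern, and the overlap of the second with these genes was not examined. They passed with the preset correlation (camera adjusted p = 1.09e-06 and 0.0331) but not with an estimated one (0.997 for each). Loss of the NRF2 repressor KEAP1 at the RNA level is argued against, since KEAP1 had a log2 fold change of 0.10 ± 0.174 with siSOX10_1. Scaling stays open for the size of the difference, as NQO1 was at -1.83 under median-of-ratios scaling but at -1.31 under quantile normalization, within 2 standard errors (0.249 each) of the bound of -1 set for it, and an unintended target of either siRNA was not tested.

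SOX10 and melanocyte genes were lowest in the batch 3 SOX10 siRNA libraries: the melanocyte list fell by a further median of -0.89 there, in 23 of 27 members. Slopes of batch 3 changes on those of batches 1 and 2 were taken among genes called without batch 3. The slope was 1.105 (interval 1.07 to 1.14) for the 1538 genes that fell and 0.918 (0.893 to 0.944) for those that rose. With 1 batch, these intervals do not measure spread between batches. Choosing genes by their changes in batches 1 and 2, and the error of those changes, lower such slopes, so the value for genes that rose excludes nothing and a deeper SOX10 loss that enlarges changes stays open. Genes that fell had a median extra change of -0.0213, and uncalled genes of like abundance shifted by -0.0724. This met the prediction set for a general loss of genes of like abundance in batch 3. But choosing genes by their falls in batches 1 and 2 also makes their extra fall look smaller, so the comparison does not decide on such a loss. For the melanocyte list, a general loss of genes of like mean abundance over all libraries is argued against (-0.0422 in 504 matched genes). Members that fell lay below that mean in the SOX10 siRNA libraries, so a loss acting at those lower values was not tested. The list's median log2 difference between batch 3 controls and the other controls was -0.0938, with untreated and siCNTL libraries pooled. The extra changes were taken against siCNTL of the same batch, which was not tested alone, so higher siCNTL values stay open. A lower level of MITF (extra change -2.24) or of SOX10 itself (-1.71) in batch 3 may account for the further fall of the list. MITF is itself a member of the list, so its fall partly restates the pattern, and with 1 batch these cannot be told apart. Part of the MITF value lies in siCNTL, where it was at 321, 349 and 465 TPM in batches 1, 2 and 3. TYR went the other way there, at 1091, 1159 and 965 TPM.

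IRF1 was at 39.3 TPM in siCNTL replicate 2 and between 5.77 and 12.7 TPM in the other 5 control libraries. RNA from SOX10 siRNA cells mixed into that library is argued against: IRF1 would need a share of 54.8%, and the 10 genes that rose most allow at most 0.765%. The other interferon gamma and IRF1 response genes had a median log2 excess of 0.192 there, which is under the bound of 0.2 set against an interferon response. The margin is smaller than 0.0282, a bootstrap spread of the median over the 22 genes in 1 library. Immediate early genes had 0.45, between the bounds of 0.2 and 0.5. These values decide neither on a small interferon response nor on a short-lived stimulation.

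Other splits of the libraries were compared with the real ones. Chance is argued against, but not excluded, for the mean of both siRNAs. There the real split gave 4820 genes in a fit with both siRNAs as 1 group. Of 84 splits 1, the real split itself, gave as many (highest other 373). The same holds for genes changed the same way by both, where 1 of 100 drawn splits gave as many (real 3165, highest other 65). In both, the highest other split set the 3 batch 3 libraries apart. For the mean, splits with every batch on each side gave at most 162 genes (26 other splits). For genes changed the same way, drawn splits with every batch in the group set as siCNTL gave at most 4 genes (31 other splits). The batches of the groups set as the siRNAs were not checked there. Splits that mix the groups carry the siRNA effect as spread within each side, so low counts there are likely in any case. For 3 against 3 libraries the 10 splits are too few for a share under 0.05: siSOX10_1 gave 4291 genes (highest other 2), siSOX10_2 gave 4539 (highest other 1), siSOX10_2 against siSOX10_1 gave 245 (highest other 1) and siCNTL against untreated gave 0 (highest other 1, with all 10 splits giving as many).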

How the results depend on the processing

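Depth is unknown and limits low genes most. Count-based tests and normalizations were not run, since the table holds no counts. Leaving out batch 3 was chosen after seeing the data, and the causes of the changes below were not tested, except where fewer libraries or a stricter threshold make them by construction. Where a library was left out, its group kept 2.

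Without 1 library, counts ran from 3024 to 4598 genes for siSOX10_1, 3402 to 4862 for siSOX10_2, 2214 to 3029 for both the same way, 3808 to 5232 for their mean and 79 to 279 for siSOX10_2 against siSOX10_1. The batch as a block gave 5180, 5320, 3800 and 6033 genes, and 488 for siSOX10_2 against siSOX10_1. Without batch 3 the counts were 5190, 5313, 3854, 6074 and 404. With a fold of at least 2, counts were 1775, 2007, 1258, 1810 and 125, and with an adjusted p under 0.01 they were 2486, 2736, 1792, 3321 and 40. The direct comparison of the siRNAs moved most, to 29 genes (22 higher) with only those groups in the fit, 123 with no filter and 138 with a pseudocount of 0.1. Against untreated cells siCNTL gave 20 genes without batch 3. Of 3165 genes changed by both, 3153 were also called with the block, 2785 without batch 3, 2754 under median-of-ratios scaling, 2750 under quantile normalization and 2604 with untreated cells as the control.

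SOX10 stayed called in every alternative run, with a log2 fold change of the mean of both siRNAs from -1.99 to -1.57 without 1 library. Without batch 3 its change was smaller, at -1.13 with siSOX10_1 and -1.42 with siSOX10_2. ITGA3 and EPHA2 also stayed called. Of 9126 gene values under alternatives, over 366 gene results, 8589 kept direction and call, 496 lost the call, 37 gained it and 4 turned direction. The turned ones were uncalled with siSOX10_2 against untreated cells, FCER1G at 0.11, MT-ATP6 at 0.13, MT-CO3 at 0.11 and MT-CO2 at 0.19. The block changed the calls of IRF1 (0.0153) and SEL1L (0.0408) with siSOX10_1, made those of FAP (0.00113) and MT-CYB (0.0470) with siSOX10_2 and of TIE1 (0.0475) in the mean, and ended those of KRT18 with siSOX10_1 (0.0546), MT-CO2 in the mean (0.0697) and the integrin list in the mean (0.0586). It also made the calls of the MHC class I list with siSOX10_2 (0.0444, and 0.408 with an estimated correlation), of the extracellular matrix and fibroblast lists in siSOX10_2 against siSOX10_1 (both 0.0447, and 0.548 and 0.274) and of the unfolded protein list in siCNTL against untreated cells (0.0308, and 0.891).

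Of 598 list values under alternatives, over 26 lists, 556 kept direction and call, 20 lost the call, 12 gained it and 10 turned direction. Of the 12 lists called, 1 remained with an estimated correlation, and 11 to 14 were called without 1 library. The estimate leaves medians as they are by construction, and the lists that lost the call there had medians of -1.88 (melanocyte), -1.30 (neural crest), 1.75 (invasive state), 0.39 (integrins), 0.56 (focal adhesion), 0.91 (extracellular matrix), 0.63 (interferon gamma), 0.41 (MHC class I), 0.80 (G2/M), 0.67 (mesenchymal) and -0.26 (mitochondrially encoded). The integrin list also lost its call with the block and without trend and robust options (adjusted p 0.0505), both with a median of 0.39, with a pseudocount of 0.1 (0.46, adjusted p 0.0533), against untreated cells (0.50, adjusted p 0.0849) and without batch 3 (0.44, adjusted p 0.103), and its median was 0.34 to 0.54 without 1 library. The mitochondrially encoded list lost it under quantile normalization (-0.21) and against untreated cells, where it turned to 0.17, and was at -0.34 to -0.17 without 1 library.

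With no filter, 6 lists gained a call: interferon-stimulated (median 0.31), G1/S (0.26), p53 (0.27), MAPK (0.36), fibroblast (0.82) and cholesterol (-0.12). These and the gains below rest on the preset correlation, and with an estimated one and the main filter the 6 lists had adjusted p of 0.684, 0.427, 0.488, 0.454, 0.427 and 0.448. Against untreated cells the interferon-stimulated (0.50) and MAPK (0.54) lists gained it, and under median-of-ratios scaling the cholesterol list (-0.21). Without 1 library the interferon-stimulated list was at 0.11 to 0.47 and the MAPK list at 0.33 to 0.50. Medians of uncalled lists turned for cholesterol against untreated cells (0.019), keratinocyte markers with no filter (-0.011) and the unfolded protein list under quantile normalization (-0.0062) and without batch 3 (-0.080). Without 1 library the unfolded protein list was at -0.21 to 0.30 and the RNA interference list at -0.11 to 0.20.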

Other observations

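The Reactome sets below were chosen after their results were seen, and none of the 727 sets passed camera with an estimated correlation. With the preset correlation 102 sets were higher and 39 lower in the mean of both siRNAs. The lowest were sets of the mitochondrial respiratory chain. In the set of respiratory electron transport and ATP synthesis, 82 of 121 genes fell and 1 rose (camera adjusted p = 1.35e-18, and 0.226 with an estimated correlation), 66 of them with each siRNA, and 12 are mitochondrially encoded. The set's median log2 fold change was -0.46, with -0.55 under median-of-ratios scaling and -0.43 under quantile normalization. Among nuclear genes, NDUFB9, a complex I subunit, went from 1140 ± 85.8 TPM with siCNTL to 542 ± 16.4 and 508 ± 8.81 TPM, and ATP5PO, an ATP synthase subunit, from 1460 ± 156 to 648 ± 30.8 and 732 ± 95.1 TPM. COX7B and NDUFAF6 had log2 fold changes of -1.22 and -1.21. Of 95 mitochondrial translation genes 48 fell and 2 rose (adjusted p = 6.32e-10, and 0.226 with an estimated correlation).

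Among higher sets, 16 of 19 interleukin 10 signalling genes rose (median 1.70, adjusted p = 1.54e-09, and 0.226 with an estimated correlation), a set largely of inflammatory cytokines and chemokines. Of 26 smooth muscle contraction genes 16 rose (median 0.69, adjusted p = 1.06e-05, and 0.226 with an estimated correlation).

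UTS2, which encodes urotensin 2, differed by batch within each group: it had 115, 115 and 9.32 TPM with siCNTL in batches 1, 2 and 3, 183, 177 and 0 TPM with siSOX10_1, and 151, 150 and 1.38 TPM with siSOX10_2. In untreated cells it had 37.3, 36.1 and 7.62 TPM.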
